A study of Mus musculus with 3 samples.

How the data were processed

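Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse T cells. Per the labels' protocols, naive CD4 T cells were sorted and activated for 72 h with IL-6 at 10 ng/ml and TGF-b at 2.5 ng/ml, a mixture that drives naive cells towards the IL-17-producing Th17 state. The cells then received IL-6 again for 1 h before chromatin was prepared. Control cells carried the conditional Stat3 allele without Cre and are called wild-type, as in the labels. STAT3-deficient cells carried the same allele with CD4-Cre, which deletes it in T cells. The titles of all 3 samples also name FoxP3-GFP. There were 3 libraries, 1 for each of wild-type H3K4me3, STAT3-deficient H3K4me3 and wild-type phospho-STAT3 (an antibody against the protein phosphorylated on serine). An input control and a phospho-STAT3 library from STAT3-deficient cells were not analysed here. Libraries were amplified for 18 PCR cycles and selected at about 250 bp including adapters, per the labels' protocols.

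The deposited files hold aligned reads, 1 line per read, with position, strand and a code that describes matching bases, and no count or signal per region. Per the submitters' processing notes, the genome build was mm9 and SICER, a caller of broad enriched islands, was used. The aligner and the version of SICER are not given in the sources used here. All reads span 25 bp, and in each deposited file no position and strand carried more than 1 read, so duplicates had been removed before deposit. Keeping all deposited reads therefore gave the same values. Coordinates are printed 1-based as the files give them, on mm9.

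Reads were moved 75 bp towards the centre of the fragment. H3K4me3 regions were called on both H3K4me3 libraries pooled, from windows of 200 bp with at least 12 reads (Poisson p of 1e-05 over a mappable share of 0.8 of the genome). Windows within 600 bp were joined and at least 2 windows were required. These regions replaced promoters, as laid down in advance for the case that the annotation given was of another build than the reads. The gene table at hand is of GRCm38.p6, so no gene was placed on a region, the preset gene lists were not run, and the search for the STAT motif was not run because no genome sequence was used here. A region with at least 50 reads in both libraries together is called marked. Ratios were scaled by setting the median log2 ratio of marked regions to 0. This takes out library efficiency, and with it any change of H3K4me3 common to all marked regions. The size rule for a differing region was a difference of at least 2-fold with an exact (Clopper-Pearson) 95% interval excluding no change. With 1 library per group no test between genotypes was possible, and the intervals cover counting error only. The reads carry no molecular identifiers, so intervals treat as independent what may not be.

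Phospho-STAT3 sites were windows of 200 bp, moved in steps of 50 bp, with at least 10 reads, reads on both strands and a Poisson p under 1e-08 against the larger of the genome-wide and the 10 kb local density. Overlapping windows were merged. The excess of a site is its highest window count minus the local expectation. A site is called strong when its excess is in the top 25% of all sites, that is at least 26.1 reads. Random lists for comparison (10000 draws) were matched on pooled reads in 20 bins, and shares carry Wilson 95% intervals. Regions and sites named in the text were fixed by rule before the data were examined: the 10 regions in each direction whose interval bound nearest 0 was farthest from 0, leaving out X and Y, and the 15 sites with the largest excess. The settings for region calling, the definition of strong sites, the comparison of lower regions with strong sites, the scan for empty intervals and the mismatch positions were chosen after the data were seen.

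On data simulated from the same regions, the size rule recovered 95% of 100 regions planted with a log2 change of 1.5 and 100% of those planted with 2.5. Without any change it called a mean of 20.2 of 10971 regions over 100 draws. On an even simulated background, the site caller found 26.9% of sites planted with 10 reads and 96.0% of those planted with 20 reads. Of 1103 calls, 0 lay away from a planted site, but uneven background, as in real libraries, was not simulated. Matched lists of 100 regions were called in 4 of 100 draws without a shift. The alternatives tried were scaling by library totals, a trend removed by read count, subtracted background, other windows and read minimums, no read shift, equal depth, other calling thresholds and island-style calling. Further ones, chosen after the data were seen, were regions called on 1 library alone, regions without X and a block of chromosome 6, other filters on sites, subtracted flanks, and matching on wild-type reads. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.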

Results

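STAT3, the transcription factor activated by IL-6 and required for the Th17 state, was profiled together with H3K4me3, a histone mark of active promoters. The wild-type H3K4me3 library held 12281399 reads, the STAT3-deficient H3K4me3 library 12075963 and the wild-type phospho-STAT3 library 10127075. Each group had 1 library, so no difference between genotypes has a replicate check. H3K4me3 regions held 7.14% of the wild-type and 8.84% of the STAT3-deficient H3K4me3 reads, and phospho-STAT3 sites held 8.90% of the phospho-STAT3 reads.

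The first question was whether the library labelled STAT3-deficient lacks part of the targeted locus. The Stat3 gene itself was not placed on mm9 here, so its reads per library are not given and the label was checked only by a scan for empty intervals. An interval of 3657 bp on chromosome 11, from 100753872 to 100757528, held 0 STAT3-deficient H3K4me3 reads. The same interval held 28 wild-type H3K4me3 reads and 73 phospho-STAT3 reads. From library totals, 27.5 STAT3-deficient reads would be expected, and a count of 0 allows up to 10.9% of that. Against a floor of 3 reads, the interval was 9.18-fold lower by library totals. Under the scaling by marked regions it was 11.4-fold lower, but the interval held too few reads to be a marked region. Neither is a lower limit, since both leave out the counting error of the 28 wild-type reads and the interval was picked for being empty. Of 98119 intervals of at least 2 kb without STAT3-deficient reads, it ranked first by the reads of both wild-type libraries summed, with 101 against 97 in the next. It also ranked first by the smaller of both counts, with 28 against 23 in the next. The ranking by the smaller count was adopted after the sum had been seen. In the reverse scan, an interval without wild-type H3K4me3 reads reached a sum of 111 and a smaller count of at most 16. On the GRCm38.p6 gene table Stat3 lies on chromosome 11.

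The comparison of both H3K4me3 libraries asks which active regions depend on the Stat3 genotype in Th17-polarised cells. H3K4me3 was much alike at most regions once their median ratio was set to 0, which would hide a change common to all of them. Of 10971 marked regions, 9424 (85.9%) lay within 0.5 log2 units of no difference after scaling. The size rule was passed by 235 regions (2.14%), of which 111 were higher and 124 lower in the STAT3-deficient library. The lowest ratios among the named regions, 10.6-fold and 9.94-fold lower, were on chromosomes 1 and 3, and a block of 9200 bp on chromosome 6 was 6.77-fold higher. In 100 simulated pairs of libraries without any change, counting noise alone put 9 to 32 of the 10971 regions past the rule, with a mean of 20.2. Variation between cultures or ChIP preparations was not simulated, so the excess over this mean is not a count of differences due to genotype.

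Among the lower regions, the one on chromosome 3 from 37130400 to 37133199 had the interval farthest from no change. It held 146 wild-type and 18 STAT3-deficient reads, a log2 ratio of -3.31 (95% interval -4.11 to -2.60). A region on chromosome 1 from 178765000 to 178765799 held 52 and 6 reads, a log2 ratio of -3.41 (-4.92 to -2.19). The region with the most wild-type reads among the 10 named was on chromosome 10 from 79535200 to 79538199, with 286 wild-type and 57 STAT3-deficient reads, 6.15-fold lower. The regions on chromosome 17 from 80111800 to 80113799 and on chromosome 8 from 122516400 to 122517799 were 7.49-fold and 6.80-fold lower. A pair of lower regions lay close together on chromosome 1. The first, from 20721000 to 20722399, held 98 wild-type and 18 STAT3-deficient reads, and the other, from 20782800 to 20784399, held 116 and 26. Their log2 ratios were -2.74 (-3.55 to -2.00) and -2.45 (-3.12 to -1.83). The remaining named lower regions were on chromosome 2 from 144994000 to 144994599 (log2 ratio -3.20), on chromosome 14 from 56384800 to 56385399 (-2.57) and on chromosome 6 from 48790000 to 48791799 (-2.21).

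Among the higher regions, the block on chromosome 6 from 124829600 to 124838799 stood apart in size, with 236 wild-type and 1960 STAT3-deficient reads and a log2 ratio of 2.76 (2.56 to 2.96). A short region nearby, from 124850400 to 124850799, held 3 wild-type and 49 STAT3-deficient reads, a log2 ratio of 3.74 (2.10 to 6.06). For the block, a gain of the mark and extra copies of the DNA could not be told apart, and the short region was not weighed. Regions on chromosome 14 from 78704200 to 78707599 and on chromosome 19 from 53604200 to 53607399 held 47 and 51 wild-type reads against 308 and 314 STAT3-deficient reads, 5.35-fold and 5.02-fold higher after scaling. On chromosome 1, the region from 137715600 to 137717799 was 5.18-fold higher and that from 163716400 to 163718999 was 4.97-fold higher. The other named regions were on chromosome 7 from 50692400 to 50694799 (log2 ratio 2.31), chromosome 9 from 115519800 to 115520799 (2.79), chromosome 18 from 89366800 to 89368199 (2.17) and chromosome 14 from 28051200 to 28052399 (2.39).

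**Figure D1:**
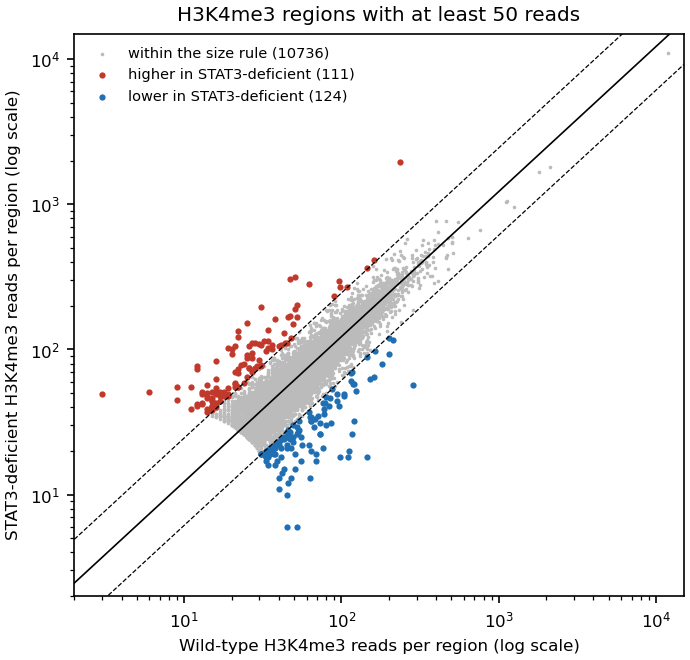
Reads per marked H3K4me3 region in the wild-type library (x axis, log scale) and the STAT3-deficient library (y axis, log scale), 1 point per region. The solid line is no difference after scaling and the dashed lines are 2-fold either way; 124 regions passed the size rule as lower and 111 as higher, and the isolated red point at 236 and 1960 reads is the block on chromosome 6.

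The counts depend on the scaling and the regions used. Scaling by library totals moves the median of marked regions by 0.32 log2 units and turns the split into 319 higher and 54 lower regions, while regions called on the wild-type library alone gave 13 higher and 117 lower, and regions called on the STAT3-deficient library alone gave 125 higher and 21 lower, a mirror image that follows from the choice of the calling library.

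The phospho-STAT3 library asks where STAT3 sits in wild-type Th17-polarised cells. It showed 26907 sites, with a median of 21 reads, 10-fold over the local expectation. The site with the largest excess over its surroundings was on chromosome 11 from 100800850 to 100801399, with 252 reads, 26.6-fold over the local density. Most sites were away from H3K4me3 regions: 32.8% (95% interval 32.2 to 33.4) lay within 2 kb of one. Seen from the regions, 47.1% of marked regions contained a site and 74.4% had one within 10 kb.

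Of the other sites with the largest excess, those on chromosome 3 from 52685000 to 52685549 and from 52358900 to 52359449 held 228 and 212 reads, both away from H3K4me3 regions. A site on chromosome 11 from 86437750 to 86438249 held 225 reads at 28.8-fold, also away from regions. Sites on chromosome 10 from 76849950 to 76850599 and from 79538000 to 79538499 held 209 and 205 reads beside H3K4me3 regions. On chromosome 1, sites from 20730400 to 20731199 and from 20749550 to 20750349 held 207 and 195 reads. They fall between the pair of lower regions on that chromosome, within a stretch of 63400 bp that held 13 sites, 12 of them strong. The site on chromosome 17 from 39979950 to 39983349 held 382 reads, but only 2.60-fold over a local density of 147, and both H3K4me3 libraries were also high there. The remaining 6 of the 15 named sites held between 190 and 209 reads, on chromosomes 3, 4, 7, 11 and 13. A further 16 strong sites crowded near the start of chromosome 11, between 3001300 and 3099200, in a stretch rich in mismatched reads. No input library was analysed here, and 12.8% of sites were also called in both H3K4me3 libraries.

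**Figure D2:**
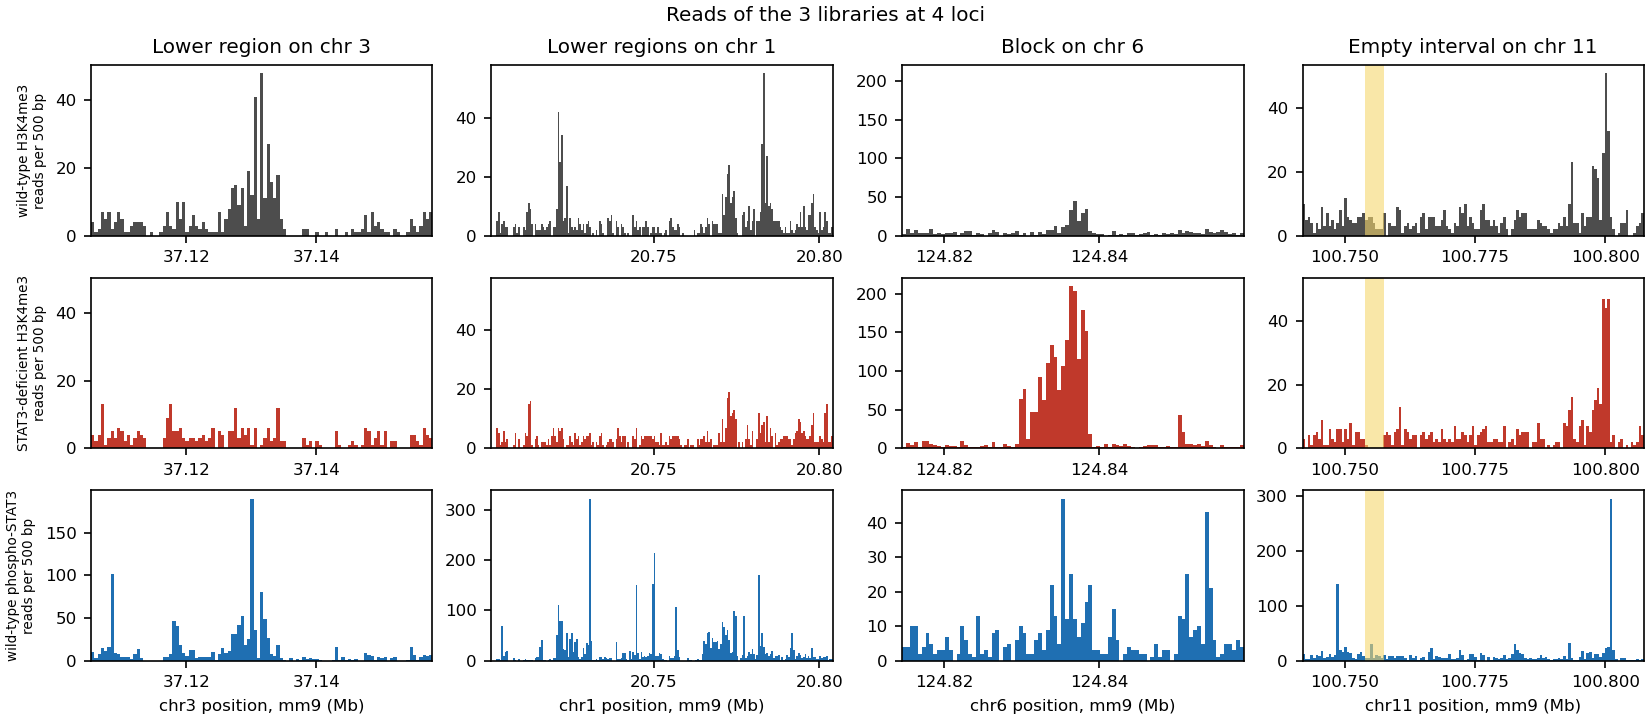
Reads per 500 bp (y axes) along mm9 positions in Mb (x axes) at 4 loci, for wild-type H3K4me3 (grey), STAT3-deficient H3K4me3 (red) and wild-type phospho-STAT3 (blue), with both H3K4me3 rows of a locus on 1 scale. The chromosome 3 region held 146 wild-type and 18 STAT3-deficient reads, the pair of lower regions on chromosome 1 flanks strong STAT3 sites, the chromosome 6 block held 236 and 1960 reads, and the shaded interval on chromosome 11 holds 0 STAT3-deficient reads.

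The 3 libraries together ask whether H3K4me3 differs where STAT3 binds. Lower regions lay near strong STAT3 sites more often than other regions did. Of 124 lower regions, 66 had a strong site within 10 kb, 53.2% (95% interval 44.5 to 61.8), against 20.95% of random regions matched on reads. All 10 named lower regions had a STAT3 site within 10 kb, as did 74.4% of all marked regions. For the 111 higher regions the share was 24.3% (17.3 to 33.1), against 23.4% in their matched lists.

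The share of lower regions was 2.47% (1.94 to 3.13) among the 2675 regions whose strongest site was in the top group of sites. It was 0.660% (0.407 to 1.07), 0.728% and 0.525% with sites of the other groups only, and 0.783% (0.518 to 1.18) with no site within 10 kb. The share of higher regions was 1.01% in the top group, 0.825%, 0.572% and 0.788% with sites of the other groups only, and 1.57% without a site. Of the 15 named sites, 10 had an interval of the H3K4me3 ratio within 1 kb that included 0, 4 of them with a ratio above 0, and 5 had an interval below 0. By library totals, 9 included 0, 4 lay below and 2 above. The lowest log2 ratios were -2.20 (-3.10 to -1.39) at the chromosome 10 site from 76849950 to 76850599 and -2.01 (-2.56 to -1.48) at that from 79538000 to 79538499, which adjoins a lower region already named. At the site with the largest excess, on chromosome 11 from 100800850 to 100801399, the ratio with the scaling by marked regions was -0.21 (-0.65 to 0.22), not distinguishable from no difference at this depth. The percentile of the 66 regions was 100 among 10000 matched lists, as a description of these libraries. With regions called on the STAT3-deficient library alone, there were 21 lower regions and the share was 38.1% against 19.9% in matched lists, at percentile 97.3, short of the upper limit set for a call. The share was not computed for the lower regions found by library totals.

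**Figure D3:**
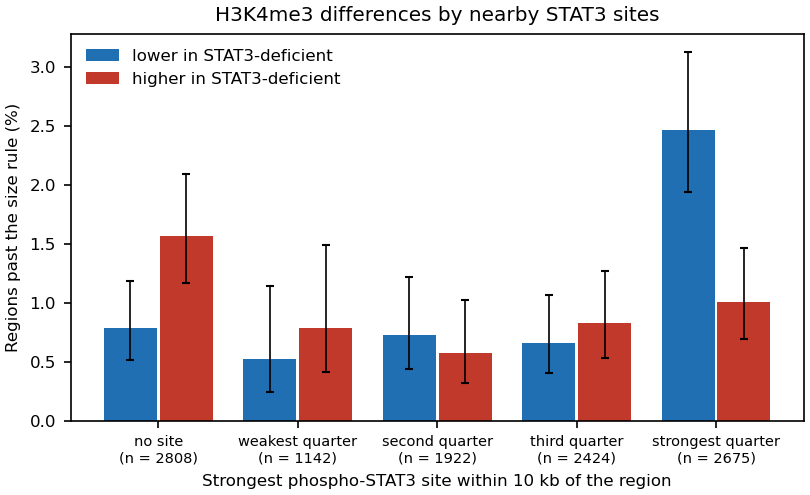
Percent of marked H3K4me3 regions past the size rule (y axis) by the strength of the strongest phospho-STAT3 site within 10 kb (x axis, no site or 4 groups of sites of equal size), lower in blue and higher in red. Bars are shares with Wilson 95% intervals that cover counting error only; the lower share is 2.47% in the strongest group and 0.783% or less in the others.

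The 8163 marked regions with a site within 10 kb had a median log2 ratio of 0.02, against -0.05 for the other 2808 regions. Bound regions make up 74.4% of the marked regions whose median the scaling sets to 0, so their median is held near 0 and says nothing of a shift common to them. The bound median lay 0.0074 above that of lists matched on reads, which share most of their members with it, and the percentile fell from 100 to 57.1 at a calling threshold of 1e-12. The direction differed between groups of regions, without a steady trend by site strength. Regions with a strong site had a median of -0.00021 against 0.0142 in matched lists, at percentile 1.23. Regions with no site within 10 kb also lay below their lists, -0.046 against -0.021, at percentile 0.01. A median below the lists was thus not particular to strong sites. From the weakest group of sites up, the other groups lay above their lists, at percentiles 99.9, 82.4 and 99.75, of which 82.4 is within the limits set for a call. Summed over the 8826 sites near H3K4me3 regions, H3K4me3 within 1 kb differed by a log2 ratio of -0.01 (-0.01 to -0.00). This direction turned to 0.31 by library totals. With flanks at 1 to 2 kb subtracted, the ratio near regions was above 0 under both scalings, 0.03 (0.02 to 0.04) by marked regions and 0.35 (0.34 to 0.36) by library totals. These flanks lie in or beside the regions and held 229869 wild-type reads, against 562008 within 1 kb. They are therefore not background alone, and the sign is not read as a result. At the 18081 sites away from regions the ratio was -0.32 (-0.33 to -0.32). Most reads there are background, and by library totals the ratio was -0.0059 (-0.01 to 0.00). After subtraction of flanks at 1 to 2 kb, the ratio away from regions was -0.24 (-0.31 to -0.16) with the scaling by marked regions and 0.08 (0.01 to 0.16) by library totals, so its direction turned with the scaling.

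**Figure D4:**
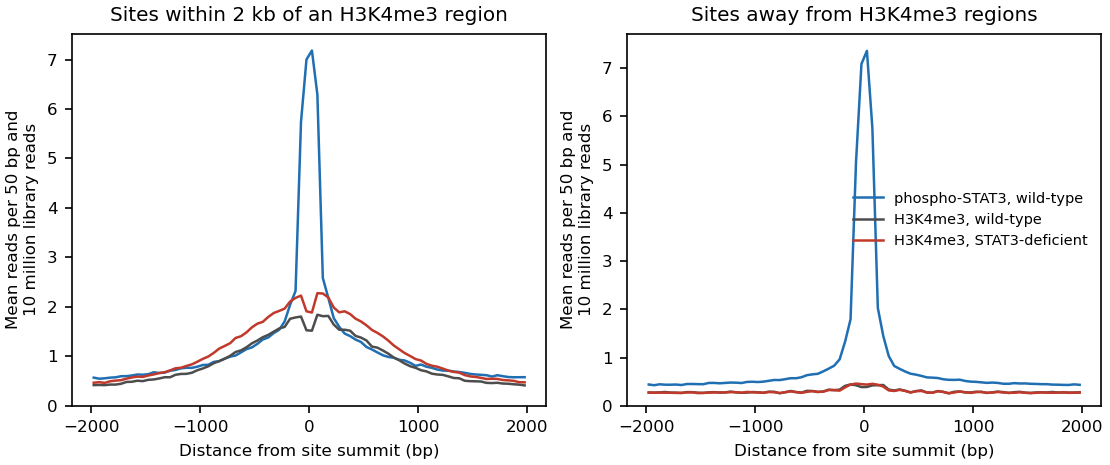
Mean reads per 50 bp, scaled to the same total for each library (y axis), by distance from the summit of phospho-STAT3 sites in bp (x axis), for the 8826 sites within 2 kb of an H3K4me3 region and the 18081 sites away from them. Lines are means over sites in each library, without the scaling by marked regions; at the sites away from regions, both H3K4me3 lines rise from 0.28 (wild-type) and 0.27 (STAT3-deficient) at the left edge to 0.44 and 0.44 in the bin 150 bp left of the summit, and cross near it.

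Across 20 chromosomes, the number of marked regions followed the number of protein-coding genes in the GRCm38.p6 table (Pearson r = 0.90, Spearman rho = 0.93, permutation p = 0.0001 for each, the smallest the permutations can give). Without chromosomes 7 and 2, r was 0.91. For phospho-STAT3 sites, r was 0.77 and rho 0.88, each with permutation p = 0.0001, and r was 0.76 without chromosomes 7 and 2. These 2 relations were the family computed, and the adjusted p-values were 0.0001. Chromosome length was not adjusted for, and longer chromosomes can hold more genes, regions and sites. No link between STAT3 sites and genes is therefore read from these values. The differing regions were spread over the chromosomes, with up to 16 lower on chromosome 2 and 12 each on chromosomes 1 and 7.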

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

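The tests of both patterns weighed here were chosen after the results were seen, as was the mismatch analysis. The mismatch code in each read, which the report's comparisons do not use, gave 6680 positions where at least 3 reads from different offsets differed from the reference in at least 30% of reads. They were far from evenly spread: 126 of 1328 bins of 2 Mb held 85.4% of them. Each stretch named next stood out because it holds at least 100 such positions in data that no comparison used. On chromosome 4 there were 1051 positions between 116 and 136 Mb and 222 between 94 and 110 Mb, and on chromosome 1 there were 658 between 78 and 94 Mb. Chromosome 11 held 523 between 96 and 120 Mb, 473 between 2 and 4 Mb and 102 between 70 and 78 Mb. Chromosome 17 held 485 between 22 and 54 Mb and 280 between 2 and 14 Mb. Further stretches were on chromosome 6 from 46 to 58 Mb with 403, chromosome 5 from 136 to 154 Mb with 272, chromosome 9 from 68 to 90 Mb with 136 and chromosome 19 from 58 to 62 Mb with 135.

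The share of non-reference reads was compared between both H3K4me3 libraries in 109 bins, and the 3 bins ranked first by Fisher's exact test on reads are given as values. No p-value is given, since reads at linked positions are not independent and each genotype had 1 H3K4me3 library. On chromosome 11, the share of non-reference reads from 116 to 118 Mb was 80.3% in the wild-type and 97.9% in the STAT3-deficient H3K4me3 library (117 and 143 reads). From 114 to 116 Mb it was 79.0% and 97.46% (124 and 118 reads), and on chromosome 17 from 24 to 26 Mb 53.5% and 75.3% (226 and 292 reads). In the wild-type phospho-STAT3 library the shares were 76.9%, 87.0% and 59.7% in the same order (130, 77 and 176 reads). Each was below the STAT3-deficient share of its bin. The positions were found mostly from wild-type reads, which made up 2 of the 3 libraries. Lower regions lay in bins rich in such positions in 21 of 124 cases (16.9%) and higher regions in 14 of 111 (12.6%), against 16.01% of all marked regions.

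The block of chromosome 6 from 124829600 to 124838799 was weighed as a gain of H3K4me3 on the resident chromosome or as extra copies of the DNA. By library totals, the STAT3-deficient reads in its 4 windows at wild-type background were 20.8-fold higher (13.9 to 32.5), against 6.91-fold in the 5 others, but windows and block were picked for such values, so this cannot support extra copies. At its edges the outer kb held 2.99% of the reads of the inner kb, a share that falls with height, and only 4 other wide regions were of like height, 2 of them with a share as low. A mark on the resident chromosome and extra copies therefore cannot be told apart, since so few regions of like height were there to compare. The labels name CD4-Cre in these cells, and the GRCm38.p6 table puts Cd4 on chromosome 6, so a candidate source is the Cre transgene, which no test here could identify.

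The interval of chromosome 11 without STAT3-deficient reads was weighed as a chance gap, as unmappable sequence or as a deletion. It was found by scanning, and the next interval came close, with 23 against 28 reads by the smaller count. At the lower bound of the expected reads, 18.3, chance would give 0.14 such gaps over the whole STAT3-deficient library, too many to exclude chance, while the 101 reads of both wild-type libraries show that the sequence can be mapped. A deletion, for which 0 reads were seen and 27.5 expected, was not tested independently, since the interval was picked for being empty. It stays open beside chance as a hypothesis, and may be part of Stat3, which the gene table puts on the same chromosome but which was not placed here.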

How the results depend on the processing

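No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. The cause was not tested for any value below unless stated. Of the 20 named regions, 19 kept direction and size rule under all 5 alternatives run on the same regions, and the region on chromosome 1 from 178765000 kept them under 4, since without read shift it held 49 reads, under the minimum of 50. Gene lists, their STAT3 binding and the STAT motif were not run, and keeping all deposited reads changed nothing since no duplicates were there. Differing regions (235, with 111 higher and 124 lower) became 373 by library totals (319 higher, 54 lower, 85.5% higher), 374 with background subtracted (176 and 198), 357 with windows of 1 kb each side (155 and 202), and 589 (172 and 417) both with a minimum of 20 reads and with none. Regions called on the wild-type library alone gave 130 (13 and 117) and on the STAT3-deficient library alone 146 (125 and 21), by construction, since a region must be high in the calling library. A removed trend, no shift, equal depth and leaving out X and the block stayed within 1.5 times. Sites (26907) became 42509 at 1e-05, 15340 at 1e-12, 49472 with the genome-wide density only and 58018 as islands. The median difference of bound regions fell to 0.00077 at 1e-12, percentile 57.1. Around sites near regions (-0.01), the log2 ratio reversed to 0.31 by library totals, 0.032 with flanks at 1 to 2 kb subtracted and 0.066 with flanks at 4 to 6 kb, and was -0.016 within 500 bp, -0.013 at 1e-05 and -0.013 at 1e-12. Away from regions (-0.32) it was -0.0059 by library totals, -0.31 within 500 bp, -0.32 at 1e-12, -0.24 with flanks at 1 to 2 kb and -0.69 with flanks at 4 to 6 kb. The last is not a local background, since those flanks touched a region at 1512 sites (8.36%). At sites near regions, the flanks at 1 to 2 kb lie in or beside the regions, so they are not background alone either. The share of lower regions with a strong site (53.2%) was 38.1% against 19.9% in matched lists (percentile 97.3) for regions called on the STAT3-deficient library. It was 57.3% against 22.5% for those called on the wild-type library, 61.6% against 21.6% with the trend removed and 46.0% against 20.7% with background subtracted, all 3 at percentile 100. The share was not computed by library totals, under which 54 regions were lower. These alternatives of regions, flanks and sites were in part chosen after the data were seen. Depth limits weak sites, since 26.9% of simulated sites of 10 reads were found.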

Other observations

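The comparisons in this part were chosen after the results were seen. A cluster of 14 strong STAT3 sites spans chromosome 1 from 20704200 to 20791950. The 4 marked regions within 50 kb of it had a median log2 ratio of -1.49, and 2 of them were lower in the STAT3-deficient library. By contrast, the cluster of 11 strong sites on chromosome 5 from 53793450 to 53886900 had 1 marked region within 50 kb, which was higher at a log2 ratio of 1.21. Of the 10 clusters with the most strong sites, the one on chromosome 1 from 20704200 alone held lower regions. The cluster of 16 on chromosome 11 from 3001300 had 1 higher and 0 lower of 7 marked regions, that of 13 on chromosome 9 from 3000100 had 0 differing of 9, and the remaining 6, without the chromosome 5 cluster, had no differing region. Without an input library, none of these clusters was checked for signal that does not come from STAT3.

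The closeness of lower regions to strong STAT3 sites was weighed as an effect of their height in wild-type cells, as phospho-STAT3 reads that follow marked regions, or as H3K4me3 that depends on STAT3. Matched on wild-type reads, random lists held a strong site in 24.1% of regions, and the 53.2% of the lower regions stayed at percentile 100. Height in wild-type reads therefore does not account for the whole pattern. Strong sites away from all H3K4me3 regions were then counted within 50 kb. Of the lower regions, 62.1% had one against 26.0% of matched lists, again percentile 100. The higher regions also had such sites more often, 39.6% (31.0 to 48.9) against 27.1%, percentile 99.8. This excess was thus not particular to the lower regions. With no input library analysed here, phospho-STAT3 reads that follow marked regions are not excluded. Dependence of the mark on STAT3 at these regions may explain the lower ones and remains a hypothesis, since 1 library per genotype was compared and no phospho-STAT3 library of STAT3-deficient cells was analysed here. The phospho-STAT3 library and the H3K4me3 library that is higher at the lower regions both came from wild-type cells. Any other difference between the cells of both genotypes is therefore confounded with such dependence, and none was tested.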
